A study of Mus musculus with 12 samples.

How the data were processed

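The study used mouse ES cells of line K3, grown, per the labels, in N2B27 medium with inhibitors and LIF, then for 3 days in N2B27 with inhibitors and doxycycline. Total RNA was isolated on silica columns (RNeasy) and labelled with biotin by a whole-transcript kit, and each of 12 samples was hybridised to 1 Affymetrix MoGene 2.0 ST array, per the labels. The deposited table held log2 expression values from 1.59 to 13.6, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; program versions are not given in the sources used here. RMA corrects background, brings all arrays to a common distribution and summarises probes to probe sets, so a change shared by most genes would not show. The scanner files were not used here, so no detection call or background level accompanies a value, and the signal of dim probe sets cannot be set against it. Of 41345 probe sets, 802 repeated another row exactly.

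Gene names came from the platform annotation supplied with the table, which can be old. It listed a gene for 25335 probe sets, exactly 1 symbol for 23521, several for 1814 and none for 16010; a probe set without a listed gene is unnamed here. Genes were counted by the 1-symbol probe set with the highest mean over all arrays, giving 22180 genes, of which 1082 had several probe sets. Chromosomes and gene order came from the RefSeq annotation of GRCm38.p6, which placed 22136 genes; the build behind the array annotation is not given in the sources used here, so no coordinates are printed.

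Groups and clones came from the sample labels, which call the 2 arrays of a clone biological replicates. All 12 arrays entered a single linear model of the 3 groups (limma 3.58.1 in R 4.3.3, with statmod 1.5.0), with clone as a random block (consensus correlation 0.0286). Tests were two-sided and adjusted by the Benjamini-Hochberg method over all probe sets. A probe set was called at an adjusted p under 0.05, and a second count required a log2 difference of at least 1. Clones of one label were compared in a model with the 6 clones as groups. The groups share replicate numbers 1 and 2, but these are numbered within clones and mark no shared culture in the labels.

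The 26 gene lists were fixed before the data were examined: naive pluripotency, core pluripotency network, formative and primed epiblast, primitive endoderm, mesoderm and definitive endoderm, neuroectoderm, trophoblast, two-cell-stage genes, feeder fibroblast markers, germline genes, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, FGF and ERK outputs, LIF and STAT3 outputs, Wnt and beta-catenin outputs, Nodal and TGF-beta outputs, DNA methylation machinery, imprinted genes, p53 targets, interferon response, cell cycle, nuclear receptors, Y-linked genes, and unfolded protein and amino acid stress. Some genes stand in more than 1 list: 9 of 23 naive pluripotency genes and 5 of 17 LIF and STAT3 outputs do. Each list was ranked against all genes with camera (preset correlation 0.01), adjusted over the lists of a comparison. With a correlation estimated from the arrays, the LIF and STAT3 list passed against WT/mock in both comparisons and the naive pluripotency list passed on the arrays labelled KO/ERRb-wt against both other groups. No other call held. For the LIF and STAT3 list the estimate was 0, below the preset 0.01, so this test was less strict for it. Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, passed 11, 5 and 18 lists in the 3 comparisons.

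The rule for named genes was also fixed before the data were examined. It took Esrrb; the 10 genes with the largest increase and the 10 with the largest decrease among called 1-symbol genes whose 4 arrays of one group all lay above the 4 of the other, and 5 and 5 for KO/ERRb-wt against WT/mock; the 10 genes in each direction of the reversal with the largest smaller of the log2 differences; up to 4 members per list with the smallest adjusted p, with members contrasted with them; and up to 5 genes per label called between clones. Predicted and non-coding models and olfactory and vomeronasal receptors were counted and not named. For each list that passed, those of the 4 members that were called are named. Outside the rule, Dppa3, Nanog, the genes of the X-linked run, and Slc22a18 and Kcnq1ot1 beside Phlda2 were chosen after their values were seen.

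The pipeline was tested on simulated data with 100 changed probe sets of each size among 41345. For KO/mock against WT/mock it recovered 45% of changes of 0.5 and 81% of changes of 1 on the log2 scale, for KO/ERRb-wt against KO/mock 56% and 90%, and for KO/ERRb-wt against WT/mock 55% and 89%. Of the simulated calls 8.03%, 8.75% and 8.28% were false, so the share was above the nominal 5%, and with no change simulated limma called 0 in each comparison.

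Alternatives were: no clone block, clone averages, the replicate number as a block, only the 2 groups compared, dim probe sets left out (log2 of at least 6 on at least 4 arrays kept), only 1-symbol probe sets, quantile normalization, centring each array on its median, a trended robust variance prior, array weights, and leaving out each array and each clone in turn. For lists, the mean over all probe sets of a gene, an estimated correlation and fry were added. After the data were seen, chromosome 14 genes were left out, Esrrb was left out of the naive pluripotency list and identical rows counted as 1.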

Results

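Gene expression was measured on whole-transcript mouse arrays in cells of K3, a mouse embryonic stem (ES) cell line, to profile genes that depend on ERRb, the orphan nuclear receptor encoded by Esrrb. The labels give 3 groups of 4 arrays each. WT/mock cells had an intact Esrrb gene, KO/mock cells carried a knockout of it, and KO/ERRb-wt cells were knockout cells that had received a lentivirus expressing ERRb. Each group held 2 clones with 2 arrays per clone, named here by clone and replicate number (clones 5-2 and 5-5, 8-3 and 8-4, and 12-1 and 12-3). Before RNA extraction all cells spent 3 days in serum-free N2B27 medium with doxycycline and a pair of kinase inhibitors, against GSK3 and MEK, that hold ES cells in the naive state. The deposited table gave log2 expression of 41345 probe sets on 12 arrays, and array medians lay between 5.00 and 5.07. For arrays, the number of clones and replicates sets the precision. Except where clones are averaged, compared with each other or left out, p-values for differences compare groups of 4 arrays from 2 clones. The clone correlation in the fit was 0.0286, so those arrays count as nearly independent. It was 0.167 with dim probe sets left out. Fits on clone averages, given below, compare 2 clones with 2. A difference between groups also holds whatever distinguishes those clones.

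Esrrb, the targeted gene, did not follow the labels. On the log2 scale its single probe set read 7.38 ± 0.00 (SD, n = 4) on the arrays labelled WT/mock, 7.66 ± 0.27 (SD, n = 4) on those labelled KO/mock and 6.73 ± 0.20 (SD, n = 4) on those labelled KO/ERRb-wt. The arrays labelled KO/mock read 7.48, 8.00, 7.74 and 7.41, all above the WT/mock values of 7.38 to 7.39. The arrays labelled KO/ERRb-wt read 6.99, 6.76, 6.50 and 6.68, all below both other groups. The log2 difference was 0.28 ± 0.13 (SE) for KO/mock minus WT/mock (limma, adjusted p = 0.324), -0.93 ± 0.13 for KO/ERRb-wt minus KO/mock (adjusted p = 0.00436) and -0.65 ± 0.13 for KO/ERRb-wt minus WT/mock (adjusted p = 0.00557). Without KO/mock clone 8-3 replicate 2 the difference between KO/mock and WT/mock was 0.17 (adjusted p = 0.538). The call between KO/ERRb-wt and WT/mock ended without clone 12-3, with an adjusted p of 0.0591. Exact two-sided permutation of the 8 single arrays gave p = 0.0286 in each of the 3 comparisons, the smallest that 4 against 4 arrays allow. It ignores that arrays share clones. Only 3 splits keep clones whole, so no small p is possible with clones as the unit. The position of the lesion and the part of the gene carried by the virus are not given in the sources used here, so the probe set may lie outside either and may check neither label. Groups are therefore called by their labels throughout, and every direction below is a difference between labelled arrays.

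**Figure D1:**
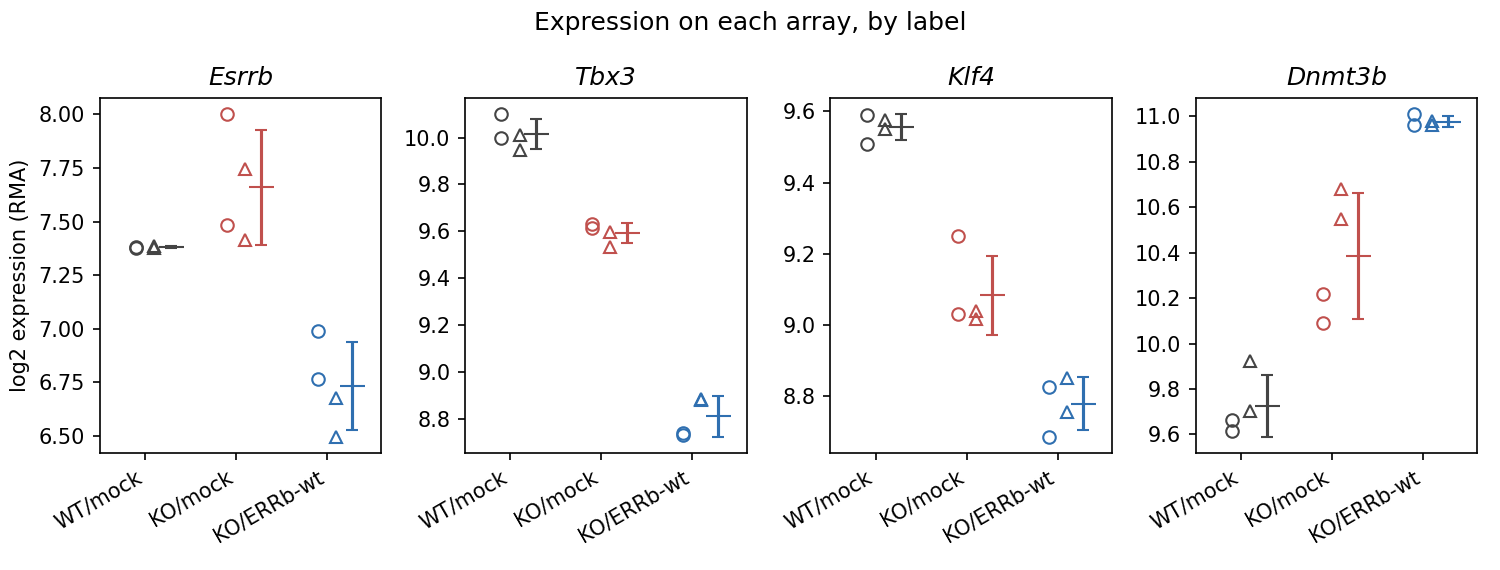
Log2 expression (vertical axis, a separate range for each gene) of Esrrb, Tbx3, Klf4 and Dnmt3b on each of the 12 arrays, by label; circles and triangles mark the 2 clones of a group, and the bar gives the mean and SD of 4 arrays. Mean Esrrb was 7.38, 7.66 and 6.73 on the arrays labelled WT/mock, KO/mock and KO/ERRb-wt, while Tbx3 read 10.02, 9.59 and 8.81.

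The arrays labelled KO/mock and WT/mock address, if the labels hold, what the knockout changed. Naive pluripotency factors were among the genes lower on the arrays labelled KO/mock: the adhesion molecule Jam2 fell by 1.02 ± 0.11 on the log2 scale (SE, 4 arrays against 4; limma, adjusted p = 0.000447), and the transcription factors Klf5, Klf4 and Zfp57 fell by 0.45, 0.47 and 0.44. The de novo DNA methylation genes Dnmt3l and Dnmt3b rose by 0.90 and 0.66. In all, 1602 of 41345 probe sets differed at an adjusted p under 0.05, 660 higher and 942 lower, of which 108 differed by at least 2-fold. Counted as genes with 1 probe set each, 1238 of 22180 differed, 469 higher and 769 lower.

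Genes of chromosome 14 made up 273 of those 1238 genes, or 22.1%, and 271 of them were lower. Over the 343 chromosome 14 genes with a mean log2 level of at least 6, the median difference between the arrays labelled KO/mock and WT/mock was -0.43 relative to the genes of the other chromosomes. On the other 19 chromosomes tested, 1 to 19 without 14 and X, the median lay between -0.02 and 0.03. The arrays labelled KO/ERRb-wt had the shift too, at -0.47 against WT/mock, and each of the 8 arrays labelled knockout lay between -0.41 and -0.47. Without chromosome 14 genes, an alternative chosen after seeing the data, 1179 probe sets were called, 587 higher and 592 lower.

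Among the genes with the largest decreases on the arrays labelled KO/mock were 3 of chromosome 14: Uggt2, a glucosyltransferase of the endoplasmic reticulum, at -1.56 ± 0.08 (SE; limma, adjusted p = 2.42e-06), the splicing factor Mbnl2 at -1.48 ± 0.14 and Dpysl2 at -1.17 ± 0.07. The X-linked homeobox gene Rhox5 read 8.62 ± 0.30 (SD, n = 4) on the arrays labelled WT/mock and 7.24 ± 0.19 on those labelled KO/mock, a difference of -1.38 ± 0.15 (SE; limma, adjusted p = 0.000448). The intermediate filament gene Des, Got1l1, Nxf3, the matrix protein gene Ccn1, the actin regulator Was and Gng12 differed by -1.33, -1.32, -1.24, -1.19, -1.18 and -1.14. Among named genes with non-overlapping arrays, which leave out predicted and non-coding models, the largest increases were those of the Y-linked gene Uty at 1.33 ± 0.19, the zinc finger gene Bcl11a at 1.27 ± 0.15, Ms4a14 at 1.25 ± 0.26, Sptlc3 at 1.19 ± 0.11, the imprinted Polycomb-related gene Sfmbt2 at 1.18 ± 0.14, Casq2 at 1.18 ± 0.24, the neuronal filament gene Ina at 1.17 ± 0.17, Gmnc at 1.10 ± 0.26, Upk1a at 1.06 ± 0.11 and Map7d3 at 0.99 ± 0.08. Only 1 of the 2 Bcl11a probe sets pointed upward. Leaving out WT/mock clone 5-2 replicate 1, KO/mock clone 8-4 replicate 1 or KO/mock clone 8-4 replicate 2 ended the calls of Ms4a14, Casq2 and Gmnc, with adjusted p up to 0.0734, 0.0586 and 0.121. WT/mock clone 5-2 replicate 2 did so for Ms4a14 and Gmnc, and each KO/ERRb-wt array for Gmnc.

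Of the 26 gene lists tested, 10 passed on the arrays labelled KO/mock against WT/mock. In the naive pluripotency list, 8 of 23 measured members were called, 1 higher and 7 lower, and 15 did not pass; adjusted over the list alone, 17 were called, 7 higher and 10 lower. Dppa3, a maternal-effect gene, rose by 0.78 ± 0.13 while Jam2, Klf5, Zfp57, Klf4 and Tbx3 fell. The list as a whole ranked lower (camera, adjusted p = 0.0272; adjusted p = 0.164 with an estimated correlation); its mean was -0.0358 and its median 0.0136, of opposite sign. Without Esrrb, an alternative chosen after seeing the data, the mean was -0.0501 and the median -0.0527 (adjusted p = 0.0184; adjusted p = 0.132 with an estimated correlation). The list's call ended without WT/mock clone 5-5 replicate 2 (adjusted p = 0.12) and with dim probe sets left out (adjusted p = 0.0606). In the latter setting the mean was -0.0409 against -0.0358. The outputs of LIF and STAT3 signalling, the cytokine pathway that sustains mouse ES cells, ranked lower (camera, adjusted p = 0.000949, and adjusted p = 0.000505 with an estimated correlation). The estimate was 0 for this list, below the preset 0.01, so the second test was the less strict one. In that list 5 of 17 members were called, all lower, among them Rhox5, Klf5, Klf4 and the tight-junction gene Ocln at -0.59 ± 0.08; adjusted over the list alone 7 were called, 1 higher and 6 lower. Klf5 lies on chromosome 14. The labels list LIF for the culture before the last 3 days and not during them. Whether LIF signalling was active at RNA extraction is not known.

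The other 8 lists passed by camera with the preset correlation but, like the naive pluripotency list, not with an estimated one. By fry, all of these but the Y-linked list (adjusted p = 0.066) passed. The core pluripotency network ranked higher (camera, adjusted p = 0.000565; adjusted p = 0.194 with an estimated correlation), with 2 of 18 members called, Dnmt3l at 0.90 ± 0.10 and the RNA-binding protein gene Lin28a at 0.58 ± 0.14; adjusted over the list alone 6 were called, all higher. Tricarboxylic acid cycle genes ranked lower (adjusted p = 0.0272; adjusted p = 0.392 with an estimated correlation), with 4 of 20 members called over all genes and adjusted over the list alone: Suclg2 fell by 0.66, Sucla2 by 0.44, Dld by 0.35 and Pdhb by 0.26. Sucla2 and Pdhb lie on chromosome 14, and the list did not pass without the genes of that chromosome (adjusted p = 0.0747). Nor did it pass with dim probe sets left out (adjusted p = 0.0764), with its mean unchanged at -0.0932. Imprinted genes ranked lower (adjusted p = 0.0355; adjusted p = 0.0524 with an estimated correlation), with 2 of 24 called, Plagl1 at -0.67 and Igf2r at -0.62, and 4 adjusted over the list alone, all lower. Germline genes ranked lower (adjusted p = 0.0491; adjusted p = 0.164 with an estimated correlation), with 5 of 22 called, 1 higher and 4 lower, and 7 adjusted over the list alone, 2 higher and 5 lower. Among them Rhox5, Mov10l1 and Taf7l fell by 1.38, 0.96 and 0.67, and Sohlh2 rose by 0.82. The mean was -0.154. Several settings ended the germline call without shrinking it. It was -0.164 with median centring (adjusted p = 0.0546), -0.162 with quantile normalization (adjusted p = 0.0659) and -0.247 with dim probe sets left out (adjusted p = 0.316). With array weights it was -0.147 (adjusted p = 0.0625). Leaving out dim probe sets ended the imprinted call too (camera, adjusted p = 0.0818), with a mean of -0.145 against -0.113.

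The unfolded protein and amino acid stress list ranked lower (adjusted p = 0.0272; adjusted p = 0.392 with an estimated correlation), with 3 of 20 called, Atf3 at -0.83 ± 0.17, Chac1 at -0.83 ± 0.20 and Nupr1 at -0.64 ± 0.14, and 7 adjusted over the list alone, all lower. The p53 targets ranked lower (adjusted p = 0.0355; adjusted p = 0.409 with an estimated correlation), with 3 of 19 called, Perp at -0.63 ± 0.14, the DNA polymerase gene Polk at -0.45 ± 0.11 and Btg2 at -0.37 ± 0.08, and 6 adjusted over the list alone, all lower. Wnt and beta-catenin outputs ranked higher (adjusted p = 0.0491; adjusted p = 0.243 with an estimated correlation), with 2 of 16 called, Lef1 at 0.96 ± 0.14 and Sp5 at 0.59 ± 0.14, and 6 adjusted over the list alone, 5 higher and 1 lower. Y-linked genes ranked higher (adjusted p = 0.0365; adjusted p = 0.392 with an estimated correlation), with 2 of 7 called over all genes and adjusted over the list alone, Uty at 1.33 ± 0.19 and Uba1y at 0.66 ± 0.15. Uty already differed between the WT/mock clones, reading 6.58 and 6.49 on clone 5-2 and 7.37 and 7.29 on clone 5-5. Leaving out dim probe sets ended the unfolded protein, p53, Wnt and Y-linked calls (camera, adjusted p = 0.0804, 0.136, 0.126 and 0.0606). Their means were then -0.227, -0.115, 0.206 and 0.785, against -0.211, -0.117, 0.156 and 0.351. The Wnt call also ended with array weights, a trended robust prior, no clone block and only the 2 groups compared (adjusted p = 0.0623, 0.0506, 0.0501 and 0.0653).

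Many of these calls ended when a single array was left out, often any of several. Leaving out WT/mock clone 5-2 replicate 1 ended those of Lin28a, Sp5, Btg2, Polk, Perp, Uba1y, Atf3, Nupr1, Chac1 and Dld, with adjusted p over all arrays left out reaching 0.108, 0.124, 0.086, 0.121, 0.07, 0.101, 0.0654, 0.0854, 0.113 and 0.0501. Of the other 11 arrays, 7 did so for Lin28a, 8 for Sp5, 5 for Btg2, 8 for Polk, 3 for Perp, 4 for Uba1y, 2 for Atf3, 4 for Nupr1 and 6 for Chac1. Single arrays also ended the list calls: 7 arrays that of the germline list (adjusted p up to 0.141) and 8 that of the Wnt list (up to 0.125). WT/mock clone 5-2 replicate 1, KO/mock clone 8-3 replicate 1 and KO/mock clone 8-3 replicate 2 ended that of the p53 list (up to 0.101), WT/mock clone 5-5 replicate 2 and KO/mock clone 8-3 replicate 1 that of the imprinted list (up to 0.0701), and WT/mock clone 5-2 replicate 1 and KO/mock clone 8-3 replicate 2 that of the Y-linked list (up to 0.133).

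With the 2 arrays of each clone averaged first, 10 probe sets were called on 2 clones against 2. Leaving out WT/mock clone 5-2 replicate 1, WT/mock clone 5-2 replicate 2, KO/mock clone 8-4 replicate 1 or KO/mock clone 8-4 replicate 2 lowered the count from 1602 to 888, 979, 988 and 952.

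The arrays labelled KO/ERRb-wt and KO/mock address, if the labels hold, what returning ERRb changed, with Esrrb itself lower on the arrays labelled KO/ERRb-wt. Naive pluripotency genes were lower on those arrays: the T-box factor Tbx3 fell by 0.78 ± 0.06 (SE, 4 arrays against 4; limma, adjusted p = 0.000137), the AKT coactivator Tcl1 by 0.56, Zfp57 by 0.39 and Nanog by 0.25. The peptidase gene Mme fell by 1.78 ± 0.12 and the signalling gene Bmp4 by 1.46 ± 0.12, while the kinase gene Pim2 rose by 1.63 ± 0.11. In all, 1329 probe sets were called, 404 higher and 925 lower, of which 44 differed by at least 2-fold. Counted as genes, 977 of 22180 differed, 274 higher and 703 lower. Of the calls, 30.4% were higher as deposited, 42.2% with quantile normalization and 21.5% with each array centred on its median.

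Mme read 7.68 ± 0.22 (SD, n = 4) on the arrays labelled KO/mock and 5.90 ± 0.16 on those labelled KO/ERRb-wt. The axon guidance gene Slit2 differed by -1.33 ± 0.12 (SE; limma, adjusted p = 0.000357), the imprinted transporter gene Slc38a4 by -1.32 ± 0.21, the fatty acid elongase gene Elovl7 by -1.30 ± 0.11, Bcl2l14 by -1.14 ± 0.08, Pudp by -1.07 ± 0.19, Cyp39a1 by -1.07 ± 0.15 and Ndrg2 by -0.99 ± 0.10; Copz2 fell by 1.00. Bmp4 and Ndrg2 lie on chromosome 14. Among the increases, the cyclic nucleotide phosphodiesterase gene Pde2a differed by 1.41 ± 0.15, the integrin gene Itga1 by 1.26 ± 0.17, Was by 1.15 ± 0.09, the fatty acid transport gene Slc27a2 by 1.07 ± 0.14, the egg-coat gene Zp3 by 0.97 ± 0.20, Prickle1 by 0.94 ± 0.15, the Kit ligand gene Kitl by 0.91 ± 0.22, Tfe3 by 0.88 ± 0.09 and Irgm1 by 0.88 ± 0.15. Both KO/mock clone 8-3 arrays, both KO/ERRb-wt clone 12-1 arrays and KO/ERRb-wt clone 12-3 replicate 2 ended the calls of Zp3 (adjusted p up to 0.0697) and Kitl (up to 0.116) when left out singly. WT/mock clone 5-2 replicate 1, WT/mock clone 5-5 replicate 1 and both KO/mock clone 8-4 arrays did so for Kitl, as did quantile normalization (adjusted p = 0.0622). Leaving out clone 8-3 ended the calls of Itga1, Slc27a2, Prickle1, Irgm1, Slc38a4, Pudp and Copz2, besides Zp3 and Kitl. The calls of Mme, Bmp4, Slit2, Elovl7, Bcl2l14, Cyp39a1, Ndrg2, Pde2a, Was and Tfe3 held without any clone.

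Of the increases named, Pim2, Was and Tfe3 are neighbours on the X chromosome. They belong to a run of 11 genes, from Praf2 to Was in the RefSeq annotation of GRCm38.p6, that are neighbours among the genes with a mean log2 level of at least 6 other than microRNA genes, all of which were called higher on the arrays labelled KO/ERRb-wt than on those labelled KO/mock, with a median difference of 0.53. On the arrays labelled KO/mock, 6 of the 11 were called lower than on WT/mock and none higher, with a median of -0.29. Both differences use the KO/mock arrays, and the run was picked by the one with KO/ERRb-wt. The other 287 X-linked genes at that level, microRNA genes left out, had medians of -0.08 and 0.01 in these comparisons.

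**Figure D2:**
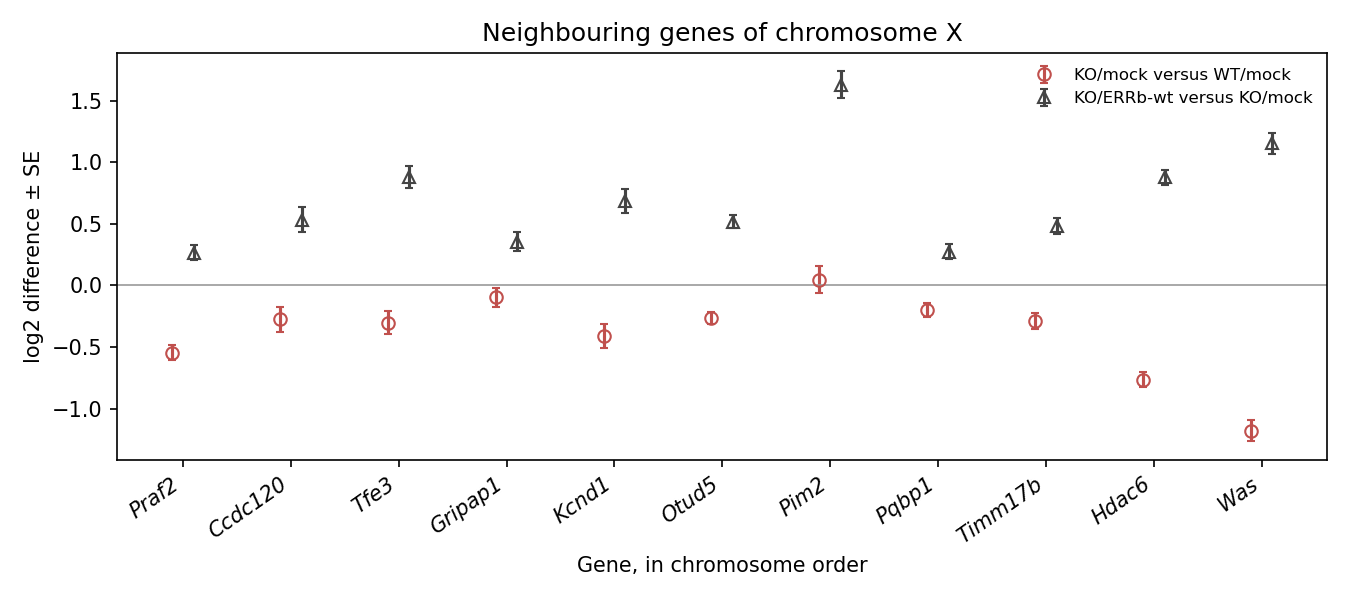
Log2 difference with its SE (vertical axis) of 11 neighbouring genes of chromosome X in chromosome order (horizontal axis), for KO/mock minus WT/mock (circles) and KO/ERRb-wt minus KO/mock (triangles). All 11 genes lie above 0 in the second comparison, with a median of 0.53, and 1 of them lies above 0 in the first. The genes were picked by the second comparison, and both use the KO/mock arrays.

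Of the 26 lists, 2 passed between the arrays labelled KO/ERRb-wt and KO/mock. In the naive pluripotency list 11 of 23 members were called, 1 higher and 10 lower; adjusted over the list alone, 14 were called, 2 higher and 12 lower. The list ranked lower (camera, adjusted p = 1.36e-07; adjusted p = 7.46e-05 with an estimated correlation), with a mean of -0.204, and Esrrb is one of its members; without it the mean was -0.172 (adjusted p = 3.1e-06; adjusted p = 0.00133 with an estimated correlation), a test chosen after seeing the data. Dppa3 was the member that rose, by 0.59 ± 0.13. Klf5 and Klf4 fell by 0.29 and 0.30. Leaving out either KO/mock clone 8-3 array or KO/ERRb-wt clone 12-3 replicate 2 ended both calls (adjusted p up to 0.0556 and 0.0736); WT/mock clone 5-2 replicate 1, KO/mock clone 8-4 replicate 2, KO/ERRb-wt clone 12-1 replicate 1, KO/ERRb-wt clone 12-3 replicate 1 and quantile normalization (adjusted p = 0.061) ended that of Klf4. Fatty acid oxidation genes ranked lower (adjusted p = 0.00296; adjusted p = 0.0885 with an estimated correlation), with 3 of 20 members called and 6 adjusted over the list alone, all lower. The list did not pass with dim probe sets left out (adjusted p = 0.219), with a mean of -0.145 against -0.148, or without clone 12-1 (adjusted p = 0.0963). Acadl, a long-chain acyl-CoA dehydrogenase, fell by 0.78 ± 0.09, and Cpt1a, which admits fatty acids to mitochondria, by 0.53 ± 0.10, and Hadh by 0.30 ± 0.07. Both KO/mock clone 8-3 arrays and both KO/ERRb-wt clone 12-1 arrays ended the calls of Cpt1a (adjusted p up to 0.0666) and Hadh (up to 0.0937) when left out singly. KO/ERRb-wt clone 12-3 replicate 2 did so for Cpt1a, and both WT/mock clone 5-2 arrays, KO/mock clone 8-4 replicate 2, KO/ERRb-wt clone 12-3 replicate 1 and quantile normalization (adjusted p = 0.0675) for Hadh.

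With clone averages limma called 0 probe sets here, with 6124 at an unadjusted p under 0.05. The count of 1329 fell to 564, 544, 680, 785 and 618 without KO/mock clone 8-3 replicate 1, KO/mock clone 8-3 replicate 2, KO/mock clone 8-4 replicate 2, KO/ERRb-wt clone 12-3 replicate 1 and KO/ERRb-wt clone 12-3 replicate 2.

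If the labels hold, a gene restored by ERRb would be called in opposite directions in these comparisons, and 77 probe sets were. Were the KO/mock and KO/ERRb-wt labels exchanged, other probe sets would qualify as restored, and those were not counted. Of the 77, 28 were lower on the arrays labelled KO/mock than on WT/mock and higher on KO/ERRb-wt than on KO/mock, and 49 went the other way. Was fell by 1.18 and rose by 1.15, the chloride transporter gene Clcn5 fell by 1.00 and rose by 0.78, and the deacetylase gene Hdac6 fell by 0.76 and rose by 0.88, all X-linked. Was and Hdac6 belong to the run of 11 neighbouring genes above. Counted as genes, 24 were lower and then higher, 6 of them in that run, so these 6 may not be separate changes. Anxa8, a chromosome 14 gene, fell by 0.98 and rose by 0.56. Perp, Abcb1b, Steap3, the Hedgehog effector gene Gli1, Serping1 and the ion channel gene Piezo1 fell by 0.63, 0.56, 0.55, 0.48, 0.46 and 0.44 and rose by 0.60, 0.68, 0.47, 0.61, 0.55 and 0.51. In the other direction, Slit2 rose by 0.78 and fell by 1.33, the calcium-binding protein gene Calb2 rose by 0.98 and fell by 0.74, the formin gene Fhod3 rose by 0.66 and fell by 0.71, and the glutamate transporter gene Slc1a3 rose by 0.61 and fell by 0.75. Zc3hav1, Sox4, Sgpp2, the laminin gene Lama1, Cdo1 and Usp44 rose by 0.67, 0.65, 0.59, 0.58, 0.56 and 0.53 and fell by 0.55, 0.54, 0.52, 0.66, 0.47 and 0.52. Leaving out KO/mock clone 8-3 replicate 1 ended at least 1 of the calls of Perp, Abcb1b, Gli1, Steap3, Sox4 and Sgpp2, with adjusted p over all arrays left out reaching 0.0979, 0.13, 0.0936, 0.0656, 0.106 and 0.0722. Other single arrays did so too, 7 for Perp, 9 for Abcb1b, 3 for Gli1, 3 for Steap3, 9 for Sox4 and 4 for Sgpp2.

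More probe sets, 190, were called in the same direction in both comparisons, 65 higher and 125 lower, Tbx3, Klf4, Klf5 and Zfp57 among the latter and Dnmt3l and Dnmt3b among the former. The call of Dnmt3b between KO/ERRb-wt and KO/mock ended without either KO/mock clone 8-3 array or either KO/ERRb-wt clone 12-3 array (adjusted p up to 0.065). Independent lists of these sizes would share 9.20 and 14.8 probe sets in the opposite directions and 6.45 higher and 21.1 lower in the same direction. That takes probe sets as independent, which the neighbouring genes of the X-linked run may not be. Both comparisons use the KO/mock arrays. In 100 simulations of unchanged groups the overlaps were 0, but KO/mock against WT/mock averaged 0.07 calls there, so an overlap was hardly possible. The correlation of log2 differences across probe sets, which are not independent replicates, averaged -0.499 against -0.0748 observed. Sharing the KO/mock arrays gives such a negative value with no change. The covariance averaged -0.0112 against -0.00338. Over the 22180 genes, which were not simulated, the observed correlation was 0.12 and the covariance 0.00411, with 55 genes opposite and 141 the same. With clone 8-3 serving the first comparison and clone 8-4 the second, 21 probe sets were opposite and 21 the same; with the clones exchanged, 33 and 269, and the covariance was 0.00313 and 0.013. The count of 77 fell to 42, 45, 47, 47 and 46 without WT/mock clone 5-2 replicate 1, KO/mock clone 8-3 replicate 1, KO/mock clone 8-3 replicate 2, KO/mock clone 8-4 replicate 2 and KO/ERRb-wt clone 12-3 replicate 2, and was 0 with clone averages.

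The arrays labelled KO/ERRb-wt and WT/mock lay farthest apart. If the labels hold, they address what still differed after ERRb was returned. Were the KO/mock and KO/ERRb-wt labels exchanged, they would address the knockout itself. Tbx3 fell by 1.21 ± 0.06 on the log2 scale on the arrays labelled KO/ERRb-wt (SE, 4 arrays against 4; limma, adjusted p = 1.46e-06), Jam2 by 1.46, Zfp57 by 0.83, Klf4 by 0.78, Klf5 by 0.74 and Nanog by 0.40. Dppa3, Dnmt3l and Dnmt3b rose by 1.37, 1.49 and 1.25. In all, 6460 probe sets were called, 2841 higher and 3619 lower, of which 410 differed by at least 2-fold; counted as genes, 4617 of 22180, 1957 higher and 2660 lower. Of the calls, 44.0% were higher as deposited, 48.0% with quantile normalization and 34.4% with each array centred on its median. Of the 1602 probe sets called for KO/mock against WT/mock, 1370 were called here in the same direction and 6 in the opposite one. Independent lists would share 128 in the same direction. Simulated unchanged groups with the same WT/mock arrays shared 0, but they averaged 0.07 and 0.04 calls, so hardly any could be shared. With one WT/mock clone per comparison 1160 or 491 were shared in the same direction, and the covariance of log2 differences was 0.0307 or 0.0256, against 0.0399 with shared arrays and 0.0112 in the simulation.

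The named decreases were Des at -2.29 ± 0.20, Mme at -2.27 ± 0.12, Got1l1 at -2.10 ± 0.17, Uggt2 at -2.06 ± 0.08 and Rhox5 at -1.93 ± 0.15 (SE; limma, adjusted p from 3e-07 to 2.45e-05). The named increases were Pde2a at 2.04 ± 0.15, Gmnc at 2.03 ± 0.26, Sfmbt2 at 1.93 ± 0.14, Casq2 at 1.89 ± 0.24 and Zp3 at 1.86 ± 0.20. Sfmbt2 read 6.57, 7.75 and 8.50 on the arrays labelled WT/mock, KO/mock and KO/ERRb-wt.

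Here 7 lists passed. The naive pluripotency list ranked lower (camera, adjusted p = 2.71e-07; adjusted p = 0.000117 with an estimated correlation), with 17 of 23 members called, 4 higher and 13 lower; adjusted over the list alone, 20 were called, 6 higher and 14 lower. LIF and STAT3 outputs ranked lower (adjusted p = 0.00246; adjusted p = 0.0012 with an estimated correlation), with 6 of 17 called, 1 higher and 5 lower, and 7 adjusted over the list alone, 2 higher and 5 lower. Rhox5, Ocln, Klf4 and Klf5 fell by 1.93, 0.92, 0.78 and 0.74. With dim probe sets left out this list did not pass (adjusted p = 0.0767), though its mean was -0.272 against -0.228 with them. As said above, the estimated correlation of the LIF and STAT3 list was 0, so that test was less strict for it. By camera, the remaining lists passed with the preset correlation and not with an estimated one. Fatty acid oxidation ranked lower (adjusted p = 0.00246; adjusted p = 0.0648 with an estimated correlation), with 8 of 20 called, 1 higher and 7 lower, and 10 adjusted over the list alone, 1 higher and 9 lower. Cpt1a, Acadl, Cpt2 and Etfdh fell by 1.28, 0.90, 0.43 and 0.29. The list did not pass with dim probe sets left out (adjusted p = 0.124), with a mean of -0.231 against -0.238. Tricarboxylic acid cycle genes ranked lower (adjusted p = 0.0139; adjusted p = 0.292 with an estimated correlation), with 9 of 20 called, 2 higher and 7 lower, and 10 adjusted over the list alone, 2 higher and 8 lower. Suclg2, Idh2, Dld and Sucla2 fell by 0.81, 0.64, 0.56 and 0.54. The core pluripotency network ranked higher (adjusted p = 0.00524; adjusted p = 0.292 with an estimated correlation), with 8 of 18 called, 6 higher and 2 lower, and 11 adjusted over the list alone, 9 higher and 2 lower. Dnmt3l, Lin28a, Tcf7l1 and Zscan10 rose by 1.49, 0.76, 0.69 and 0.55. The formative and primed epiblast list ranked higher (adjusted p = 0.0442; adjusted p = 0.357 with an estimated correlation), with 7 of 17 called, 5 higher and 2 lower over all genes and adjusted over the list alone; Dnmt3b, the epithelial factor Grhl2 and Lef1 rose by 1.25, 1.25 and 0.90, and the keratin gene Krt18 fell by 0.56. With the replicate number as a block this list's adjusted p was 0.0503. Of its members, 4 lie on chromosome 14, and without them its median was 0.22 against 0.118, so they did not raise it. Wnt and beta-catenin outputs ranked higher (adjusted p = 0.0281; adjusted p = 0.174 with an estimated correlation), with 9 of 16 called, 8 higher and 1 lower, and 10 adjusted over the list alone, 8 higher and 2 lower; Sp5, Lef1 and the Wnt inhibitor gene Notum rose by 1.10, 0.90 and 0.79, and Bmp4, a chromosome 14 gene, was lower (adjusted p = 1.64e-05). Leaving out KO/mock clone 8-4 replicate 2 or KO/ERRb-wt clone 12-1 replicate 1 ended the calls of the formative (adjusted p up to 0.0876) and Wnt (up to 0.0547) lists, and WT/mock clone 5-2 replicate 1 or KO/ERRb-wt clone 12-3 replicate 1 that of the formative list. With dim probe sets left out, the tricarboxylic acid cycle, formative and Wnt lists did not pass by camera (adjusted p = 0.21, 0.0774 and 0.0779). Their means did not shrink, at -0.152, 0.285 and 0.261 against -0.152, 0.249 and 0.239. With clone averages 2251 probe sets were called.

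The other 14 lists passed by camera in none of the 3 comparisons, though some of their members were called. The lowest adjusted p by camera was 0.06 for primitive endoderm, 0.62 for mesoderm and definitive endoderm, 0.326 for neuroectoderm, 0.357 for trophoblast, 0.78 for two-cell-stage genes and 0.25 for feeder fibroblast markers, the lists that stand for other cells a culture could hold. It was 0.105 for oxidative phosphorylation, 0.3 for glycolysis, 0.247 for FGF and ERK outputs, 0.192 for Nodal and TGF-beta outputs, 0.192 for DNA methylation machinery, 0.22 for the interferon response, 0.152 for the cell cycle and 0.247 for nuclear receptors. For KO/ERRb-wt against WT/mock, 10 of 13 DNA methylation genes were called, 6 higher and 4 lower, and 10 of 18 glycolysis genes, 5 higher and 5 lower. Fry tests a list against no change rather than against other genes. By fry, 7 of the 14 were shifted higher in that comparison: primitive endoderm (adjusted p = 0.00242), nuclear receptors (adjusted p = 0.00464), DNA methylation machinery and the cell cycle (both adjusted p = 0.0177), feeder fibroblast markers (adjusted p = 0.0222), FGF and ERK outputs (adjusted p = 0.0338) and neuroectoderm (adjusted p = 0.0383). A list's median, mean and test differed in sign in 9 of the results: naive pluripotency and two-cell-stage genes for KO/mock against WT/mock, germline genes for both comparisons with KO/ERRb-wt, FGF, LIF and imprinted lists for KO/ERRb-wt against KO/mock, and glycolysis and interferon for KO/ERRb-wt against WT/mock.

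Clones of one label were compared with 2 arrays on each side. Between clones 5-5 and 5-2 of WT/mock limma called 0 probe sets, with 3113 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0718. Between 8-4 and 8-3 of KO/mock it called 2, the imprinted genes Phlda2 at -3.13 (adjusted p = 0.00623) and Mest at 1.13 (adjusted p = 0.00623). Between 12-3 and 12-1 of KO/ERRb-wt it called 7, none with a single listed gene, and 2 of the 7 only repeated the values of another of them on all arrays.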

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

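The tests of explanations and the other splits were chosen after the result was seen, apart from the comparison of the X-linked run between the KO/mock clones. Each of 110 named genes was examined within each group of 4 arrays for a single array far from the rest, and 10 of 330 groups, or 3.03%, had one; chance gives about 1 in 20. On the log2 scale these were Bcl11a at 7.22 on KO/mock clone 8-4 replicate 2 (the others at 6.95), Klf4 at 9.25 on KO/mock clone 8-3 replicate 2 (9.02 to 9.04), Sucla2 at 8.57 on KO/ERRb-wt clone 12-3 replicate 1 (8.44 to 8.46), Prickle1 at 6.27 on WT/mock clone 5-5 replicate 2 (5.73 to 5.76) and Tfe3 at 9.86 on KO/ERRb-wt clone 12-3 replicate 2 (9.75 to 9.76). On WT/mock clone 5-2 replicate 2, Irgm1 was low at 4.25 (4.70 to 4.77) and Lama1 at 6.53 (6.81 to 6.87). Cdo1 was low at 8.49 on KO/ERRb-wt clone 12-3 replicate 2 (8.59 to 8.60), and on KO/mock clone 8-4 replicate 1 Dld was low at 9.73 (9.89 to 9.92) and Hadh at 10.6 (10.7 to 10.8).

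Other splits of the 8 arrays of a comparison into 4 and 4 were fitted in the same way, with the clone correlation estimated on 2000 probe sets. In each comparison 1 of the 35 splits, the real one, gave as many calls: 1555 for KO/mock against WT/mock, 1212 for KO/ERRb-wt against KO/mock and 6295 for KO/ERRb-wt against WT/mock, where the highest other split called 1. That share, 0.0286, is the smallest that 35 splits allow. The other splits mix labels that differ, which widens the spread within their groups, so few calls were likely there in advance. Arrays of a clone are also not independent, so the splits cannot exclude chance. Only 3 splits keep clones whole, too few for a share under 0.05, and the highest of the others called 0.

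The Esrrb signal went against the labels. A single mislabelled array is argued against by the gap of 0.42 between the lowest array labelled KO/mock and the highest labelled KO/ERRb-wt: no array stood among the other group. An exchange of the KO/mock and KO/ERRb-wt labels would need naive pluripotency genes to be lower on the arrays labelled KO/ERRb-wt, and their mean difference without Esrrb itself was -0.172 (camera, adjusted p = 3.1e-06), so an exchange remains a candidate explanation. A probe set outside the lesion or the transgene stays open as well, since the array has 1 Esrrb probe set and nothing in the tables shows which exons it reads. Clone differences unrelated to ERRb, or an effect of the virus on the endogenous gene, were not tested.

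The shift of chromosome 14 on the 8 arrays labelled knockout was -0.406 for KO/mock minus WT/mock as deposited, when other genes were at 0.0261. A scaling of whole arrays is argued against, since it moves all genes of an array alike. With every array centred on its median the values were -0.416 and 0.0163, but centring could not change the gap between them. Quantile normalization, which could, gave -0.417 and 0.0183. The chromosome 14 shift did not follow the level of Esrrb either. Relative to the genes of other chromosomes it was -0.0246 between the arrays labelled KO/ERRb-wt and KO/mock, whose Esrrb signals differed by -0.93. A difference in copies of chromosome 14 between the WT/mock and the knockout clones is a candidate explanation. It needs all parts of the chromosome to shift, and the weakest of 3 parts shifted by -0.385, with other genes not subtracted. Whether knockout clones would have lost a copy or WT/mock clones gained one was not tested.

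The run of 11 neighbouring X-linked genes from Praf2 to Was was lower on the arrays labelled KO/mock and higher on those labelled KO/ERRb-wt. It was picked by its difference between KO/ERRb-wt and KO/mock. Such a choice favours genes that read low on the KO/mock arrays, so the fall against WT/mock is not separate support. Random gene orders gave as large a running median over 11 genes in a share of 0.015 of 1000 for KO/ERRb-wt minus KO/mock, which argues against chance order there. For KO/mock minus WT/mock the share was 0.153. It refers to the largest running median of any region scanned, 0.301 on X. The run itself, with a median of -0.287 there, was not tested alone, and chance order stays open. The run was not peculiar to a single KO/mock clone: the medians relative to WT/mock were -0.344 in clone 8-3 and -0.25 in clone 8-4, and 0.248 and 0.203 in clones 12-1 and 12-3. A change over the whole X chromosome is argued against by the other 287 X-linked genes, at -0.0772 between KO/ERRb-wt and KO/mock. A response to ERRb and a regional difference between the founding cells of the groups both stay open, since clones and labels coincide.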

How the results depend on the processing

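Leaving out chromosome 14 genes, leaving Esrrb out of the naive pluripotency list and counting identical probe sets as 1 were chosen after seeing the data. Among the log2 differences and list means reported, the sign changed only for the gene list naive pluripotency, KO/mock versus WT/mock. Its mean went from -0.0358 to 0.00612 without clone 5-5 (adjusted p = 0.266) and its median from 0.0136 to -0.0527 without Esrrb. With clone averages the called counts were 10, 0 and 2251 for KO/mock against WT/mock, KO/ERRb-wt against KO/mock and KO/ERRb-wt against WT/mock, with 5136, 6124 and 10012 at an unadjusted p under 0.05 (limma), 10 and 0 at 2-fold in the first comparisons, and 0 reversed; Esrrb differed by -0.93 between KO/ERRb-wt and KO/mock (adjusted p = 0.137). Of 261 calls of single genes, 58 held with clone averages, 216 with only the 2 groups compared, 246 with quantile normalization and 235 with the replicate number as a block; of 19 list calls, 10, 16, 18 and 18 did, 5 with dim probe sets left out and 4 with an estimated correlation. The naive pluripotency list passed in all 3 comparisons without Esrrb, but not for KO/mock against WT/mock with an estimated correlation (adjusted p = 0.132). Each label holds 2 clones, so clones and labels coincide, and no background signal accompanies the values of dim probe sets.

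For KO/mock against WT/mock, 531 were called without clone 5-2 and 560 without clone 8-4; at 2-fold, 53 with 1-symbol probe sets, 172 without clone 5-5 and 71 without clone 8-4. For KO/ERRb-wt against KO/mock, 777 were called with only the 2 groups compared, 2024 with dim probe sets left out, 145 without clone 8-3, 761 without 12-1 and 333 without 12-3; at 2-fold, 29 with dim probe sets left out, 17 with 1-symbol probe sets, 29 without 8-3, 81 without 8-4 and 96 without 12-1. For KO/ERRb-wt against WT/mock, 3245 were called without 5-2 and 3931 without 12-3, and 224 at 2-fold with 1-symbol probe sets; Esrrb differed by -0.50 without 12-3. The reversal counted 47 with only the 2 groups compared, 122 with dim probe sets left out, 34 without 5-2, 24 without 8-3 and 35 without 12-3. Between clones, 37, 19 and 33 were called with dim probe sets left out, 1-symbol probe sets and a trended robust prior. Fewer tested probe sets or arrays enter some of these; the cause was not tested otherwise.

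Without single arrays the counts ranged from 888 to 1841, from 544 to 1399 and from 4822 to 6526, the reversal from 42 to 76 and the clone count from 6 to 11. With the replicate number as a block 1365, 973 and 6011 were called, 1309, 937 and 5853 of them shared with the counts reported; between clones, arrays of equal number had correlations averaging 0.0356 and above 0.1 in 1 of 15 pairs, so the numbers do not pair the arrays.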

Other observations

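The genes and comparisons here were chosen after the values were seen. Between sister clones, the imprinted genes Phlda2 and Mest were called, both in the KO/mock pair. Phlda2, a growth-restraining gene of the placenta, read 7.52 and 5.05 on the log2 scale in clones 5-2 and 5-5, 8.03 and 4.89 in clones 8-3 and 8-4, and 6.75 and 5.15 in clones 12-1 and 12-3; limma called it in the KO/mock pair (adjusted p = 0.00623) and in neither other pair (adjusted p = 0.0718 and 0.206). Slc22a18, from the same imprinted domain, was lower in the second clone of each pair, by 0.85, 0.61 and 0.39, with adjusted p of 0.112, 0.273 and 0.598. Kcnq1ot1, the non-coding RNA that silences this domain, was higher in the second clone of each pair, by 0.76, 0.92 and 0.33, with adjusted p of 0.141, 0.126 and 0.682. Mest, on another chromosome, read 10.90 in clone 8-3 and between 11.57 and 12.03 in the other 5 clones. No explanation was tested.

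Imprinted genes also moved in both directions between labels. Plagl1 was lower on the arrays labelled KO/mock than on WT/mock and lower again on those labelled KO/ERRb-wt, with means of 8.93, 8.25 and 7.64, while Peg3 read 10.26, 10.52 and 11.10 and differed between KO/ERRb-wt and KO/mock by 0.59 ± 0.09 (SE; limma, adjusted p = 0.00621). Zfp57, a zinc finger protein that protects imprints, read 10.66, 10.22 and 9.83.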
